A study of Mus musculus with 6 samples.

How the data were processed

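RNA was measured by poly(A)-selected, stranded sequencing in colonies grown from pancreatic cells of adult C57BL/6 mice. Per the labels' protocols, cells with high surface CD133 (the protein encoded by Prom1) and low CD71 (the transferrin receptor, encoded by Tfrc) were sorted from dissociated pancreas, exposed overnight to lentiviral vectors, and plated in methylcellulose with Matrigel, RSPO1 (a secreted enhancer of Wnt signalling), nicotinamide, exendin-4, activin B, serum and conditioned medium under puromycin selection. Colonies were collected after 3 weeks. Each knockdown used a pool of 5 shRNA clones, against Glis3 or against CD133, while the control was a single shRNA with no mammalian target. The 6 libraries form 3 groups of 2, named by their titles as replicates 1 and 3 of each group. Each column of the table was matched to its sample by the name given in the sample's description, and all 6 columns were used.

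The authors deposited 1 table of RPKM values (reads scaled by transcript length and library size) with 2 decimals for 11164 genes. The submitters' processing notes name bcl2fastq 2.18.0.12, TopHat2, HTSeq and the mouse build mm10, without order or settings. The gene annotation, the library total behind the deposited RPKM values, any step between samples and the use of strand in counting are not given in the sources used here. The lowest per-gene maximum in the table was 1.00 RPKM, so the table holds genes that reached that level in at least 1 library, and genes outside it are not analysed here. A gene under this level in every library therefore has no value.

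Depth was estimated from the steps of low values, because reads counted as whole numbers give an RPKM that is a whole multiple of the value of 1 read. For genes with 1 basic GENCODE M21 transcript (GRCm38, the assembly of mm10) under 1200 bases and values under 3 RPKM, depths from 3 to 80 megareads (M) were scanned. The best depths were 26.8 M and 29.2 M for control libraries 1 and 3, 27.1 M and 28.4 M for Glis3 shRNA libraries 1 and 3, and 25.7 M and 27.4 M for CD133 shRNA libraries 1 and 3. At these depths 63.2% to 68.1% of the values used came out whole within 0.15 read, against 30% by chance, and each score lay above the highest of 100 scans with shuffled lengths. The reads themselves were not recovered, since transcript lengths of the authors' annotation are not known here, and no count test was run. Of the genes in the table, 11000 (98.5%) had a GENCODE transcript.

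Values were analysed as log2(RPKM + 1) without further scaling, for the 10829 genes with a mean of at least 1 RPKM over the 6 libraries. A linear model with 3 group means was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a variance trend, leaving 3 residual and 3.69 prior degrees of freedom. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and a gene was called past the threshold at an adjusted p under 0.05. Every adjusted p of a gene given in the results comes from this limma model, and standard errors (SE) and 95% confidence intervals are the moderated ones. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values.

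Before the data were examined, 32 gene lists were fixed, along with the tests, the alternatives and a rule for which genes to name. The 26 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over 78 tests (26 lists in 3 comparisons). Each was also tested by camera with the correlation estimated from the residuals, and by fry. With an estimated correlation, camera takes its p from the 3 residual degrees of freedom, so few lists could pass over 78 tests. For Wnt ligands in the Glis3 knockdown the estimated correlation was -0.111, under the preset, yet the unadjusted camera p rose from 0.00221 to 0.0506. A call lost in this way therefore does not by itself show that inter-gene correlation produced it. The directional p of fry asks whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction. Neither compares the list with other genes. Values of fry given in the results are directional unless called mixed. The rule named Glis3 and Prom1; the 12 largest rises and 12 largest falls of each knockdown among genes past the threshold whose 2 knockdown libraries both lay beyond both controls (6 and 6 between the knockdowns); up to 4 members past the threshold per list, or 2 by smallest p where none passed; and the 10 genes per direction with the largest change shared by both knockdowns. Predicted and unnamed loci were counted but not named, as were clone-derived symbols, and a few genes that the rule picks are not reported here.

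The fit was tested on simulated data with each gene's mean over all libraries, its moderated variance and a random set of changed genes. Noise was drawn independently for each gene and library, and far fewer genes were changed than were called in the data. The shares recovered and the false calls hold for that setting and were not measured for noise shared between genes. For the Glis3 comparison, 80.6% of 1.5-fold, 95.5% of 2-fold and 100% of 4-fold changes were recovered, with 12 false calls (6.1% of calls). For the CD133 comparison the shares were 76.1%, 94% and 100%, with 18 false calls (9.1% of calls). Because both knockdowns share the control libraries, the correlation and covariance of their fold changes were set beside 100 simulations of unchanged groups. The alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 RPKM, quantile normalization, median centring, an equal RPKM sum, no variance trend or a robust one, only the 2 compared groups in the fit, the replicate number as a block, and leaving out each library in turn. With 1 library left in a group, that library is assumed to vary like the other groups. Such a fit has fewer residual degrees of freedom and less precision for that group, so a lost call need not mean a smaller change. A further alternative, which removes trends with transcript length and GC content, was added after seeing the data.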

Results

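Gene expression was measured in colonies grown for 3 weeks from sorted adult mouse pancreatic cells with high CD133 and low CD71, a fraction the series describes as progenitor-like. The series asks how Glis3, CD133 and Wnt signalling are connected in the self-renewal of these cells. Colonies carried a control shRNA, a pool of shRNAs against Glis3 (a zinc-finger transcription factor of the Gli-related family), or a pool against CD133 (the pentaspan membrane glycoprotein encoded by Prom1), with 2 libraries per group. The estimated depth in megareads (M) was 26.8 M and 29.2 M for control libraries 1 and 3, 27.1 M and 28.4 M for the Glis3 knockdown, and 25.7 M and 27.4 M for the CD133 knockdown. RPKM sums per library lay between 267688 and 279122, and the 10 most abundant genes held 7.7% to 9.5% of them. Across genes, Pearson's r of log2 values was 0.995 between the control libraries, 0.992 between the Glis3 knockdown libraries and 0.995 between the CD133 knockdown libraries, and 0.979 to 0.99 between libraries of different groups; genes are not independent replicates. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries alone. The control was 1 shRNA and each knockdown a pool of 5, a difference from control that both knockdowns share. The library kit keeps the strand, but whether strand was used in counting is not stated, so values of genes that overlap on opposite strands, and of close paralogs, are less certain. Exons of Col4a1, Cyp51, Fen1, Kif7, Pfkp and Vil1 overlap those of a neighbouring gene on the opposite strand, and exons of Atp5o overlap those of Donson on the same strand.

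Each pool lowered its own target and left the other target near its control level. Glis3 (ENSMUSG00000052942.13, chromosome 19: 28258851 to 28680077, minus strand, GRCm38) fell from 25.1 ± 1.29 RPKM in control colonies to 12.6 ± 0.955 in the Glis3 knockdown (SD, n = 2 each). That is a log2 fold change of -0.94 (95% confidence interval -1.10 to -0.78, adjusted p = 0.00281) or 50.3% of control. Prom1 (ENSMUSG00000029086.15, chromosome 5: 43993620 to 44102032, minus strand) fell from 197 ± 8.61 RPKM to 92.0 ± 5.64 in the CD133 knockdown (SD, n = 2 each), a log2 fold change of -1.09 (interval -1.27 to -0.92, adjusted p = 0.00874) or 46.6% of control. In the Glis3 knockdown Prom1 was at 107.1% of control (log2 fold change 0.10, interval -0.08 to 0.28, adjusted p = 0.42), and in the CD133 knockdown Glis3 was at 97.4% (log2 fold change -0.04, interval -0.20 to 0.13, adjusted p = 0.757). RNA of one target therefore did not change detectably with knockdown of the other. The Glis3 call held without any single library. That of Prom1 was lost without control library 1 (log2 fold change -1.14, adjusted p = 0.0737) and without control library 3 (log2 fold change -1.05, adjusted p = 0.0597), and was kept without each of the other libraries.

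**Figure D1:**
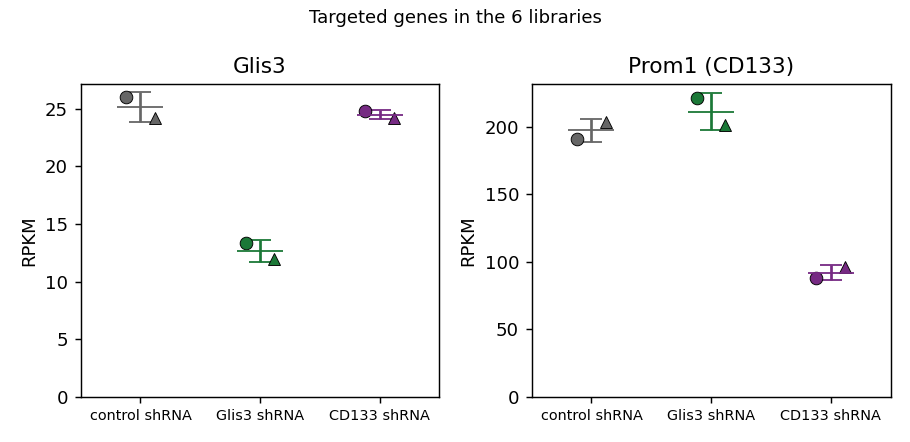
RPKM of Glis3 (left) and Prom1, the CD133 gene (right), in replicate 1 (circles) and replicate 3 (triangles), with the group mean and SD (lines and bars, n = 2), for control, Glis3 shRNA and CD133 shRNA colonies. Glis3 lies between 11.96 and 13.31 RPKM in the Glis3 knockdown and above 24 in both other groups, and Prom1 between 88.03 and 96.00 in the CD133 knockdown and above 191 in both other groups.

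The Glis3 knockdown was compared with control to find which genes depend on Glis3 in these colonies. The falls of Pglyrp3, Ch25h and Mmp13 and the rises of Ces1g and Cdo1 were the largest among genes with assigned names. Pglyrp3, a secreted bactericidal peptidoglycan-binding protein, fell from 34.2 ± 2.04 to 4.45 ± 0.049 RPKM (SD, n = 2 each; log2 fold change -2.69, SE 0.215, adjusted p = 0.00387). Ch25h, the enzyme that makes 25-hydroxycholesterol, fell from 36.9 to 5.37 RPKM (log2 fold change -2.57, SE 0.223, adjusted p = 0.00436), and the collagenase Mmp13 fell by 2.14 (SE 0.094, adjusted p = 0.000762). Gpx3 (plasma glutathione peroxidase) fell by 1.90, Tns1 (tensin 1, a focal adhesion protein) by 1.77, Reg1 (a pancreatic secreted lectin) by 1.74, Trf (transferrin) by 1.73, Hp (haptoglobin) by 1.70, Lbp (lipopolysaccharide binding protein) by 1.69, Chil1 (a chitinase-like protein) by 1.61 and Gpc3 (glypican 3) by 1.61. Cdo1, the cysteine dioxygenase, rose from 5.44 ± 0.156 to 34.4 ± 2.19 RPKM (log2 fold change 2.46, SE 0.093, adjusted p = 0.000554), and the carboxylesterase gene Ces1g from 0.3 to 12.99 RPKM (log2 fold change 3.27, SE 0.54, adjusted p = 0.0154).

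Among the other large rises were Ces1f (a carboxylesterase) at 1.86, Obp2b (an odorant binding protein) at 1.77, Mt2 (metallothionein 2) at 1.73, Cytip (a cytohesin interactor) at 1.66, Aldh3a1 (an aldehyde dehydrogenase) at 1.66, Gsta1 (a glutathione transferase) at 1.63, B4galnt2 (a glycosyltransferase) at 1.60, Nrn1 (neuritin) at 1.53, Cpm (carboxypeptidase M) at 1.48 and Ugt8a (a galactosyltransferase of glycolipid synthesis) at 1.38 on the log2 scale. The Ces1, Gsta, Reg, Mup and Obp2 genes belong to families of close paralogs, among which reads are hard to assign. Of the 24 genes with the largest rises and falls, not all of them named, 6 were still past the threshold without control library 1, 9 without control library 3, and at least 22 without each other library. Without Glis3 shRNA library 3, the value of Ces1f was 1.15.

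Wnt ligand genes fell in the Glis3 knockdown. Of the 8 ligands measured, 4 fell and 4 did not pass. Wnt10a fell from 7.20 ± 0.12 to 2.54 ± 0.156 RPKM (SD, n = 2 each; log2 fold change -1.21, SE 0.114, adjusted p = 0.0052). Wnt16 fell from 2.38 to 0.455 RPKM (log2 fold change -1.21, SE 0.171, adjusted p = 0.0108), Wnt7a from 25.8 to 15.5 RPKM (log2 fold change -0.71, SE 0.135, adjusted p = 0.0222) and Wnt7b, the most abundant ligand, from 80.5 to 66.2 RPKM (log2 fold change -0.28, SE 0.065, adjusted p = 0.0394). Adjusted over the list alone, 5 fell. Among the members that did not pass, Wnt4 had a log2 fold change of -0.32 (adjusted p = 0.0693), Wnt5a 0.18, Wnt5b 0.21 and Wnt9a 0.24. The list had a median log2 fold change of -0.30 and lay below other genes by camera (adjusted p = 0.00908, but adjusted p = 0.654 with an estimated correlation), while fry gave an adjusted p of 0.00736. Without control library 1 or 3 no ligand passed singly, and 3 passed without each of the other libraries. The list's median was -0.33 without control library 1 and -0.27 without control library 3.

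**Figure D2:**
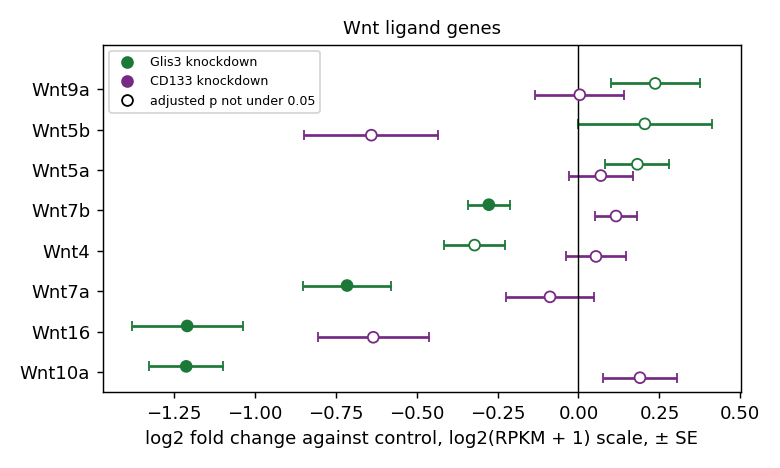
Log2 fold change against control (x axis) of the 8 measured Wnt ligand genes (y axis) in the Glis3 and the CD133 knockdown, with the SE as bars and open points where the adjusted p was not under 0.05. In the Glis3 knockdown 4 ligands lie below 0 with filled points, and in the CD133 knockdown all 8 points are open.

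The other Wnt lists were not called in the Glis3 knockdown. Among 22 receptors and secreted regulators, Rnf43 (a ubiquitin ligase that removes Frizzled receptors) rose by 0.31 and Fzd8 (a Frizzled receptor) fell by 0.27, neither of them over the list alone, while 20 did not pass (median 0.01, between -0.05 and 0.08 over the alternatives, camera adjusted p = 0.742). Of 25 intracellular components, 2 fell, also when adjusted over the list alone: Ctnnb1, which encodes beta-catenin, from 599.7 to 467 RPKM (log2 fold change -0.36, SE 0.083, adjusted p = 0.038) and Tle3 (a transcriptional corepressor) by 0.34. The median of that list was 0.09 and its camera adjusted p was 0.987. Among 17 Wnt target genes, 2 rose, over all genes and over the list alone, with Ephb2 (an ephrin receptor) at 0.43 and Rnf43, and 15 did not pass (median 0.07, camera adjusted p = 0.883). Camera placed the receptor and component lists below other genes although their medians and means were above 0. Each of these single-gene calls was lost without control library 1 and without control library 3, where no member of the 3 lists passed.

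Genes of cell division and of DNA synthesis rose together in the Glis3 knockdown. Of 35 cell cycle genes 33 rose, 0 fell and 2 did not pass, with a median log2 fold change of 0.77. Examples were the kinases Melk at 1.02 (SE 0.124, adjusted p = 0.0079) and Aurka at 0.98, the mitotic entry factor Cdca3 at 0.95, and the proliferation marker Mki67 at 0.95, or 0.59 without Glis3 shRNA library 3. Of 32 DNA replication genes 27 rose and 5 did not pass (median 0.49), with Rrm2 (a subunit of ribonucleotide reductase) at 1.13 (SE 0.136, adjusted p = 0.00784), Uhrf1 (maintenance of DNA methylation) at 0.98, Tk1 (thymidine kinase) at 0.79 and Prim1 (DNA primase) at 0.72. Cholesterol synthesis genes rose too, 22 of 25 with 3 not past the threshold (median 0.51, or 0.32 with a pseudocount of 5): Idi1 (isopentenyl diphosphate isomerase) at 1.00, Hmgcs1 (HMG-CoA synthase) and Stard4 (a sterol carrier) at 0.82 each, and Cyp51 (lanosterol demethylase) at 0.72. The rises numbered 35, 32 and 24 when adjusted over the list alone. By camera the adjusted p was 2.17e-17 for cell cycle, 1.23e-13 for DNA replication and 1.1e-12 for cholesterol synthesis, but adjusted p = 0.654, 0.688 and 0.654 with an estimated correlation. None of the 3 lists passed by fry (adjusted p = 0.095, 0.12 and 0.0585). Without control library 1, none of these genes passed singly. Without control library 3, 1 cell cycle, 0 DNA replication and 5 cholesterol synthesis genes passed, and without Glis3 shRNA library 3, 25, 10 and 12.

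Inflammatory and TGF-beta family genes lay mostly lower in the Glis3 knockdown. Of 30 genes of the TGF-beta, activin and BMP pathway, 9 fell, 2 rose and 19 did not pass (median -0.17). The activin subunit genes Inhbb and Inhba fell by 1.22 (SE 0.181, adjusted p = 0.0121) and 1.09 (SE 0.092, adjusted p = 0.00436), while Id3 (an inhibitor of helix-loop-helix factors) rose by 1.17 (SE 0.079, adjusted p = 0.0021). Of 25 NF-kB targets and cytokines, 7 fell, 3 rose and 15 did not pass (median -0.23), with the chemokine gene Ccl2 at -1.10 (SE 0.126, adjusted p = 0.00689), the adhesion molecule Icam1 at -1.10, Lcn2 (lipocalin 2) at -0.997 and Cxcl1 at -0.88. Adjusted over the list alone, 13 fell and 5 rose in the TGF-beta list, and 14 fell and 6 rose in the NF-kB list. The camera adjusted p was 0.000312 and 0.000616, but adjusted p = 0.654 and 0.688 with an estimated correlation. Neither list passed by fry (adjusted p = 0.151 and 0.271). Without control library 1, 2 TGF-beta and 1 NF-kB gene passed, and the TGF-beta median was -0.11. Without control library 3 these counts were 2 and 3, without Glis3 shRNA library 3 they were 5 and 4, and Lcn2 stood at -0.63 without that library.

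The list of p53 targets, not every member of which is induced by p53, lay higher in the Glis3 knockdown. Of its 25 genes, 4 rose, 2 fell and 19 did not pass (median 0.28). Ckap2 (a mitotic spindle protein) stood at 0.88 and Trp53inp1 (a stress protein) at 0.64. Bbc3 (a BH3-only inducer of apoptosis) stood at 0.61 and Gadd45a (a growth arrest gene) at -0.66. Adjusted over the list alone, 16 rose and 3 fell. The camera adjusted p was 0.0114 (adjusted p = 0.809 with an estimated correlation), a call lost without control library 3 (median 0.22) and without Glis3 shRNA library 3 (median 0.19), and the median was 0.45 without Glis3 shRNA library 1. Among 42 primary cilium genes, 3 rose, 2 fell and 37 did not pass, over all genes and over the list alone. Foxj1, which the list included although it is the master regulator of motile cilia, fell from 61.4 ± 4.73 to 20.6 ± 4.43 RPKM (log2 fold change -1.54, SE 0.153, adjusted p = 0.0057). Tulp3 (a ciliary trafficking adaptor) and the intraflagellar transport gene Ift27 rose by 0.46 and 0.41, and Ift57 fell by 0.30. The cilium list had a median of -0.09, or -0.15 with median centring (camera adjusted p = 0.0308, but adjusted p = 0.792 with an estimated correlation). It lost its call without control library 1 (median -0.06), without Glis3 shRNA library 1 (median -0.08) and with median centring, and its median was -0.06 without Glis3 shRNA library 3. No single p53 target or cilium gene passed without control library 1 or 3, and 2 and 3 did without Glis3 shRNA library 3.

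Lists that track RNA quality and handling moved as well. All 49 ribosomal protein genes had fold changes below 0 in the Glis3 knockdown (median -0.18, or -0.12 with quantile normalization), beside the proliferation and cholesterol genes that rose, although 5 fell singly, such as Rpl7 by 0.30 and Rpl23 by 0.28, and 44 did not pass. None passed over the list alone, and none without any single library left out in turn. The list's camera adjusted p was 3.29e-14 (adjusted p = 0.688 with an estimated correlation). Of 25 immediate early and dissociation stress genes, 3 fell, over all genes and over the list alone: Maff by 0.73, Junb by 0.44 and Ier5 by 0.29, all transcription-linked early response genes. The median of that list was -0.06 and its camera adjusted p 0.0114 (adjusted p = 0.809 with an estimated correlation). Its call was lost with quantile normalization and without control library 1, where the median was 0.03, and the median was -0.20 without control library 3 and -0.13 without Glis3 shRNA library 1. No early gene passed singly without control library 1 or 3 or without Glis3 shRNA library 3.

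Cell identity genes changed singly in the Glis3 knockdown, with no list called by camera. Of 20 progenitor factors, 3 rose (Aldh1a1, a retinaldehyde dehydrogenase, at 0.54, and the transcription factors Nkx6-1 at 0.49 and Pdx1 at 0.28), and 17 did not pass (median 0.05, or -0.01 with median centring, camera adjusted p = 0.658). Of 22 ductal markers, Elf3 (an epithelial transcription factor) rose by 0.37, Bicc1 (an RNA-binding protein) and the bicarbonate transporter Slc4a4 fell by 0.48 and 0.39, and 19 did not pass (median 0.02, or -0.08 without Glis3 shRNA library 1, against a mean of -0.02, camera adjusted p = 0.523). Of 7 endocrine markers measured, Nkx6-1 and Cpe (carboxypeptidase E) rose, the latter by 0.56, and 1 marker fell (median 0.48, but 0.08 without Glis3 shRNA library 1 and 0.19 without control library 1, camera adjusted p = 0.457). Among 10 gastric and mucous markers, Anxa13 (annexin A13) rose by 1.25, Dmbt1 (a mucosal scavenger receptor) by 0.68, and Reg3g (an antibacterial lectin) and Tff2 (a trefoil peptide) fell by 1.33 and 1.005 (median 0.12, but -0.08 at a minimum mean of 5 RPKM and -0.03 without Glis3 shRNA library 3, and mean 0.06, yet below other genes by camera, adjusted p = 0.829). Adjusted over the list alone, the counts were 3 rises among progenitor factors, 1 rise and 2 falls among ductal, 2 and 1 among endocrine, and 3 and 3 among gastric markers. Of 5 Schwann and neural markers, Cnp (a myelin enzyme) rose by 0.23 and the adhesion molecule Ncam1 fell by 0.95 (median -0.08, camera adjusted p = 0.223), also over the list alone. Without control library 1, 1 gastric marker and no member of the other 4 lists passed. Without control library 3, 1 ductal, 1 endocrine and 1 gastric marker passed, and without Glis3 shRNA library 3, 1 progenitor factor, 2 ductal, 2 endocrine, 1 gastric and 1 neural marker.

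Few markers of the other cell types that the sort could have carried along were measured. Fn1 (fibronectin), the 1 mesenchymal marker tested, fell by 1.02 in the Glis3 knockdown (SE 0.054, adjusted p = 0.000987) and by 0.38 in the CD133 knockdown (SE 0.054, adjusted p = 0.0159). Reg1 was the tested acinar marker. The immune markers Cd14 and Cd68 had log2 fold changes of -0.32 (adjusted p = 0.14) and 0.11 (adjusted p = 0.532) in the Glis3 knockdown and of -0.24 and 0.04 in the CD133 knockdown. The endothelial markers Egfl7 and Esam stood at -0.02 and 0.00, then 0.04 and -0.06, and Tfrc, the CD71 gene and an erythroid marker, at 0.26 (adjusted p = 0.108) and 0.10 (adjusted p = 0.493). These 5 lists had fewer than 5 tested members and were not tested as lists, and mitochondrially encoded genes are not analysed here. The call of Fn1 in the CD133 knockdown was lost without control library 1, control library 3 or CD133 shRNA library 1.

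The remaining pathway lists were not called in the Glis3 knockdown with all 6 libraries and the chosen settings. Among 22 Notch genes 1 rose and 2 fell, Rfng at 0.35, Lfng at -0.31 (both glycosyltransferases that modify Notch) and Maml1 (a coactivator) at -0.25 (median -0.05, camera adjusted p = 0.108). Of 9 Hedgehog genes, Gas1 (a coreceptor) fell by 0.75 (median -0.04, camera adjusted p = 0.0978). Of 25 Hippo and Yap genes 3 rose and 4 fell, including Tgfb2 (a TGF-beta ligand) at 0.70, the kinase Nuak2 at -1.04, the receptor kinase Axl at -0.57 and the scaffold Wwc1 at -0.45 (median -0.02, or 0.02 without control library 1, camera adjusted p = 0.185). Counts over each of these 3 lists alone were the same. Among 15 interferon genes, 2 rose, among them the peptide transporter Tap1 by 0.48, and Bst2 (tetherin) fell by 0.29, with 3 rises and 1 fall over the list alone (median 0.17, camera adjusted p = 0.527). Of 25 unfolded protein response genes 4 rose and 2 fell, with the transcription factor Xbp1 at -0.89, Herpud1 at 0.40, Asns (asparagine synthetase) at -0.34 and the chaperone Calr at 0.29, and 4 and 4 over the list alone. The median of that list was 0.04, its mean -0.03 and its camera adjusted p 0.658, with other genes higher. Of 24 glycolysis and hypoxia genes 3 rose (Egln3, a prolyl hydroxylase, by 0.43; the hexokinase Hk1 by 0.39; Pfkp, a phosphofructokinase, by 0.38), also over the list alone, with a median of -0.02 against a mean of 0.02 (camera adjusted p = 0.658). Among 25 basement membrane genes 1 rose and 5 fell, with the laminin Lama4 at -0.62, the integrins Itgb5 at -0.53 and Itga5 at -0.36 and the collagen Col4a1 at 0.36 (3 and 6 over the list alone, median -0.04, camera adjusted p = 0.092). Of 36 oxidative phosphorylation genes, Atp5o and Ndufb8 rose by 0.26 and 0.24, neither of them over the list alone (median 0.09, camera adjusted p = 0.108). The oxidative phosphorylation median was 0.01 without control library 1 and 0.18 without control library 3. It was called higher without the latter, with a pseudocount of 5, with quantile normalization and with an equal RPKM sum. The Hedgehog (median -0.03) and Hippo (median -0.07) lists were called lower without control library 3, and the Notch list at a minimum mean of 5 RPKM. Without control library 1 or control library 3 no member of these 8 lists passed.

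In all, 909 genes rose and 491 fell in the Glis3 knockdown among 10829 tested (limma), of which 26 rose and 58 fell by at least 1 on the log2 scale. At an unadjusted p under 0.05 there were 3305. The 2 knockdown libraries lay on one side of both controls in 59.6% of all tested genes, against 33.3% for exchangeable libraries. Genes are not independent, so this share can stray from 33.3% without an effect of the knockdown. All 1400 called genes lay so too, which the threshold nearly ensures with 2 libraries per group. The number past the threshold was 21 without control library 1 (2579 at an unadjusted p under 0.05), 88 without control library 3 and 508 without Glis3 shRNA library 3. Rises made up 64.9% of calls, but 50.8% with quantile normalization, 44.7% with median centring, 47.5% with length and GC trends removed and 66.9% with an equal RPKM sum, so the excess of rises depends on the scaling. Camera called 10 of the 26 lists, 4 higher and 6 lower. With an estimated correlation it called 0 (0 at an unadjusted p under 0.05), and fry called 1, the Wnt ligands (8 at an unadjusted p under 0.05).

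The CD133 knockdown was compared with control to find which genes depend on CD133. Among genes with assigned names, Ces1g, Duox2 and Ctla2a rose most and Pglyrp3 fell most. Duox2, a hydrogen peroxide-producing oxidase of epithelia, rose from 2.69 ± 0.622 to 16.0 ± 8.38 RPKM (SD, n = 2 each; log2 fold change 2.12, SE 0.371, adjusted p = 0.0216), and Vil1 (villin, an actin bundler of microvilli) from 7.63 to 25.6 RPKM (log2 fold change 1.62, SE 0.298, adjusted p = 0.024). Ces1g rose by 2.52, Ctla2a (a cysteine protease inhibitor) by 2.06, C4bp (a complement regulator) by 2.05, Clca3b (a chloride channel accessory protein) by 1.84, Atg9b (an autophagy protein) by 1.70, Ndnf (a secreted neurotrophic factor) by 1.62, the phosphatase regulators Ppp2r2c and Ppp1r1b by 1.53 and 1.499, Eps8l3 by 1.46 and B4galnt2 by 1.27. Pglyrp3 fell to 8.59 ± 3.46 RPKM (log2 fold change -1.92, SE 0.215, adjusted p = 0.0111). Gpx3 fell by 1.47, Tmem178 by 1.45, Mup20 (a major urinary protein) by 1.44, Hp by 1.44, Trf by 1.40, Rbp4 (retinol binding protein) by 1.36, Fmo2 (a flavin monooxygenase) by 1.35, Apcs (serum amyloid P) by 1.33, Csrnp1 by 1.31 and the cytochrome P450 gene Cyp4b1 by 1.17. None of the 24 genes with the largest rises and falls passed without control library 1 or without control library 3, and 6 passed without CD133 shRNA library 1 and 23 without CD133 shRNA library 3.

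Ribosomal protein genes fell together in the CD133 knockdown. Of 49, 42 fell, 0 rose and 7 did not pass, with a median log2 fold change of -0.37, or -0.24 with quantile normalization. Rplp2 fell from 196 ± 6.55 to 142.6 ± 8.13 RPKM (SD, n = 2 each; log2 fold change -0.46, SE 0.063, adjusted p = 0.0151), and Rps12 and Rplp1 fell by 0.46 and 0.45. Immediate early and dissociation stress genes fell with them, 7 of 25 with 18 not past the threshold (median -0.28): Socs3 (a cytokine signalling inhibitor) by 1.01 (SE 0.117, adjusted p = 0.0119), the transcription factors Klf2 by 0.74 (0.45 without control library 1), Maff by 0.73 and Fos by 0.68. Adjusted over the list alone, 48 ribosomal protein genes and 11 early genes fell. The camera adjusted p was 3.61e-33 and 1.75e-07, but adjusted p = 0.654 for both with an estimated correlation. Neither list passed by fry (adjusted p = 0.0628 and 0.225). No member of either list passed singly without control library 1, control library 3 or CD133 shRNA library 1, and 10 and 4 passed without CD133 shRNA library 3. The median of the early genes was -0.14 without control library 1 and -0.18 without CD133 shRNA library 1. Reads of ribosomal protein genes are also hard to separate from those of their many processed pseudogenes.

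Proliferation and cholesterol genes rose in the CD133 knockdown, where the ribosomal protein genes fell. Of 35 cell cycle genes 21 rose and 14 did not pass (median 0.53, or 0.35 with a pseudocount of 5), with Aurka at 0.84 (SE 0.133, adjusted p = 0.0193), the cyclins Ccne1 at 0.70 and Ccnb2 at 0.64, and Kif23 (a cytokinesis kinesin) at 0.61. Of 32 DNA replication genes 10 rose and 22 did not pass (median 0.33, or 0.21 with a pseudocount of 5), among them Rrm2 at 0.93, Uhrf1 at 0.71 and the flap endonuclease Fen1 at 0.59. Of 25 cholesterol synthesis genes 21 rose and 4 did not pass (median 0.46), with Idi1 at 0.80, Hmgcs1 at 0.79, Cyp51 at 0.71 and Msmo1 (a sterol oxidase) at 0.63. In cell cycle and replication 31 and 23 rose adjusted over the list alone, and 23 rose and 1 fell in the cholesterol list. By camera the adjusted p was 7.02e-12 for cell cycle, 7.03e-07 for DNA replication and 1.33e-10 for cholesterol synthesis, but adjusted p = 0.688, 0.809 and 0.654 with an estimated correlation. None of the 3 lists passed by fry (adjusted p = 0.151, 0.214 and 0.066). No gene of these 3 lists passed singly without control library 1, control library 3 or CD133 shRNA library 1, and 8, 3 and 16 passed without CD133 shRNA library 3.

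Interferon, basement membrane and p53 genes lay higher in the CD133 knockdown. Of 15 interferon genes 3 rose, among them Tap1 at 0.58 and Stat2 at 0.57, and 12 did not pass (7 rose over the list alone, median 0.22, or 0.11 at a minimum mean of 5 RPKM). Of 25 basement membrane and integrin genes, the laminin Lama3 rose by 0.80, the collagen Col18a1 by 0.73 and the integrin Itgb6 by 0.51, Itgb5 fell by 0.51, and in all 4 rose, 1 fell and 20 did not pass (10 and 1 over the list alone, median 0.18, or 0.12 with length and GC trends removed). Of 25 genes of the p53 list 9 rose, 1 fell and 15 did not pass (13 and 2 over the list alone, median 0.27). Eda2r (a death receptor family member) stood at 0.71, Ckap2 at 0.69, Bbc3 at 0.58 and Phlda3 (an Akt inhibitor) at 0.57. The camera adjusted p was 0.00429, 0.023 and 0.031, but adjusted p = 0.654, 0.654 and 0.848 with an estimated correlation. By fry the interferon and basement membrane lists each had an adjusted p of 0.0369. The interferon call was lost at a minimum mean of 5 RPKM, the basement membrane call without control library 3 (median 0.18), and the p53 call with an equal RPKM sum and without control library 3 (median 0.21). No member of these lists passed singly without control library 1, control library 3 or CD133 shRNA library 1, and 1 interferon, 5 basement membrane and 3 p53 genes did without CD133 shRNA library 3.

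Activin genes fell in the CD133 knockdown too. Among 30 genes of the TGF-beta, activin and BMP pathway 6 fell, 2 rose and 22 did not pass (10 and 4 over the list alone), with Inhbb at -0.96 (SE 0.181, adjusted p = 0.0253), Inhba at -0.75, the receptor Tgfbr1 at -0.68 and Id3 at 0.71. The median was -0.02, or 0.01 with an equal RPKM sum, so the list as a whole was near 0 while several members moved (camera adjusted p = 0.0114, adjusted p = 0.654 with an estimated correlation). Of 25 Hippo and Yap genes 2 rose and 2 fell (3 and 3 over the list alone), with Amotl2 (an angiomotin) at -0.56 and Ankrd1 (a Yap-induced ankyrin repeat protein) at 0.49 (median -0.07, or -0.12 with median centring, camera adjusted p = 0.0353, adjusted p = 0.688 with an estimated correlation). The TGF-beta call was lost without control library 1 (median -0.01) and with quantile normalization, and the median was -0.10 without control library 3 and -0.11 without CD133 shRNA library 3. The Hippo call was lost without control library 1 (median -0.04), without CD133 shRNA library 1 (median -0.08), with quantile normalization, with median centring and at a minimum mean of 5 RPKM, and its median was -0.04 without CD133 shRNA library 3. No member of either list passed singly without control library 1, control library 3 or CD133 shRNA library 1.

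Wnt ligand genes were not called in the CD133 knockdown. None of the 8 passed, over all genes or over the list alone, with Wnt5b at -0.64 (adjusted p = 0.0913), Wnt16 at -0.63 (adjusted p = 0.0586) and Wnt10a at 0.19 (adjusted p = 0.308). The median of the ligands was 0.03, between -0.04 and 0.08 over the alternatives, their mean -0.12 and the camera adjusted p 0.491. Some feedback regulators of the pathway rose: Notum (a secreted Wnt deacylase) from 12.2 to 25.5 RPKM (log2 fold change 0.96, SE 0.219, adjusted p = 0.039), Rnf43 by 0.43 and Axin2 (a scaffold of beta-catenin degradation induced by Wnt) by 0.54 (SE 0.118, adjusted p = 0.0346). Porcn (the acyltransferase of Wnt ligands) rose by 0.48, the coreceptor Lrp5 by 0.29 and Dvl1 (dishevelled) by 0.44. Of 22 receptors and secreted regulators 4 rose and 1 fell (5 and 3 over the list alone, median -0.04 against a mean of 0.04, camera adjusted p = 0.332). Of 25 intracellular components 1 rose, and none over the list alone (median 0.07, camera adjusted p = 0.527). Of 17 target genes 3 rose (4 over the list alone, median 0.12, camera adjusted p = 0.392). Without CD133 shRNA library 1 Notum stood at 0.60 and Axin2 at 0.36. These single-gene calls were lost without control library 1, control library 3 or CD133 shRNA library 1.

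Ductal and progenitor genes changed singly in the CD133 knockdown. Of 22 ductal markers 6 rose, 2 fell and 14 did not pass (9 and 2 over the list alone, median 0.17, camera adjusted p = 0.352, called higher with quantile normalization). Spp1 (osteopontin), among the most abundant transcripts of the colonies, fell from 6611 ± 172 to 3665 ± 759.6 RPKM (SD, n = 2 each; log2 fold change -0.87, SE 0.175, adjusted p = 0.029), whereas Car2 (carbonic anhydrase) rose from 150.5 to 286 RPKM (log2 fold change 0.93, SE 0.119, adjusted p = 0.0138) and the keratins Krt19 and Krt8 by 0.66 and 0.61. Of 20 progenitor factors the transcription factor genes Foxa1 (0.57), Nkx6-1 (0.52), Sox9 (0.41) and Hnf4a (0.31) rose and 16 did not pass (6 rose and 1 fell over the list alone, median 0.03, camera adjusted p = 0.561). Among 7 endocrine markers 2 rose, Cpe by 0.97 and Nkx6-1 (2 and 1 over the list alone, median -0.05 and mean -0.15 with camera above other genes, adjusted p = 0.987). Of 10 gastric and mucous markers the water channel Aqp5 fell by 0.66 (1 and 1 over the list alone, median -0.01 against a mean of 0.05, camera adjusted p = 0.742). Of 5 Schwann and neural markers Nes (nestin) rose by 0.68 (1 and 1 over the list alone, median -0.09 against a mean of 0.07, camera adjusted p = 0.699). Reg1 stood at 0.65 (adjusted p = 0.268). No member of these lists passed without control library 1 or 3, and without CD133 shRNA library 1 only 1 endocrine marker did.

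The other lists were not called in the CD133 knockdown. Among 22 Notch genes 1 rose and 2 fell (3 and 4 over the list alone), with the coactivators Maml3 at -0.49 and Maml1 at -0.34 and Nrarp (a Notch feedback regulator) at 0.38, a median of 0.00 against a mean of -0.03, and a camera adjusted p of 0.248. No Hedgehog gene of 9 passed, over all genes or over the list alone, with Kif7 (a kinesin of Gli signalling) at -0.31 and the receptor Ptch1 at -0.23 (median -0.04, camera adjusted p = 0.0581). That list was called lower with a pseudocount of 0.1, with quantile normalization, with length and GC trends removed and without control library 3 (median -0.05). Its median was -0.09 without CD133 shRNA library 1. Of 25 NF-kB genes and cytokines 3 rose, also over the list alone, Tnf by 0.87, Ccl20 by 0.85 and Ccl2 by 0.66 (median 0.03, or -0.02 with quantile normalization and -0.03 with median centring, camera adjusted p = 0.908). Of 25 unfolded protein response genes 1 rose and 2 fell (6 and 7 over the list alone), Herpud1 at 0.57, Ppp1r15a (a phosphatase subunit of the stress response) at -0.61 and Asns at -0.37, with a median of 0.04 against a mean of -0.07 (camera adjusted p = 0.407). Of 24 glycolysis and hypoxia genes 2 rose, Hk1 by 0.26 and Ero1l (an oxidoreductase) by 0.20 (3 over the list alone, median -0.02 against a mean of 0.01, camera adjusted p = 0.709). Of 42 primary cilium genes Ift27 and Tulp3 rose by 0.40 and 0.31 (1 over the list alone, median -0.05, camera adjusted p = 0.179), with Foxj1 at -0.48 (adjusted p = 0.0898). None of 36 oxidative phosphorylation genes passed, over all genes or over the list alone, with Sdha at 0.18 and Cycs at 0.21 (median 0.05, camera adjusted p = 0.756). The median was -0.02 without control library 1 and 0.12 without control library 3, where the list was called higher. Each of these single-gene calls was lost without control library 1 and without control library 3.

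**Figure D3:**
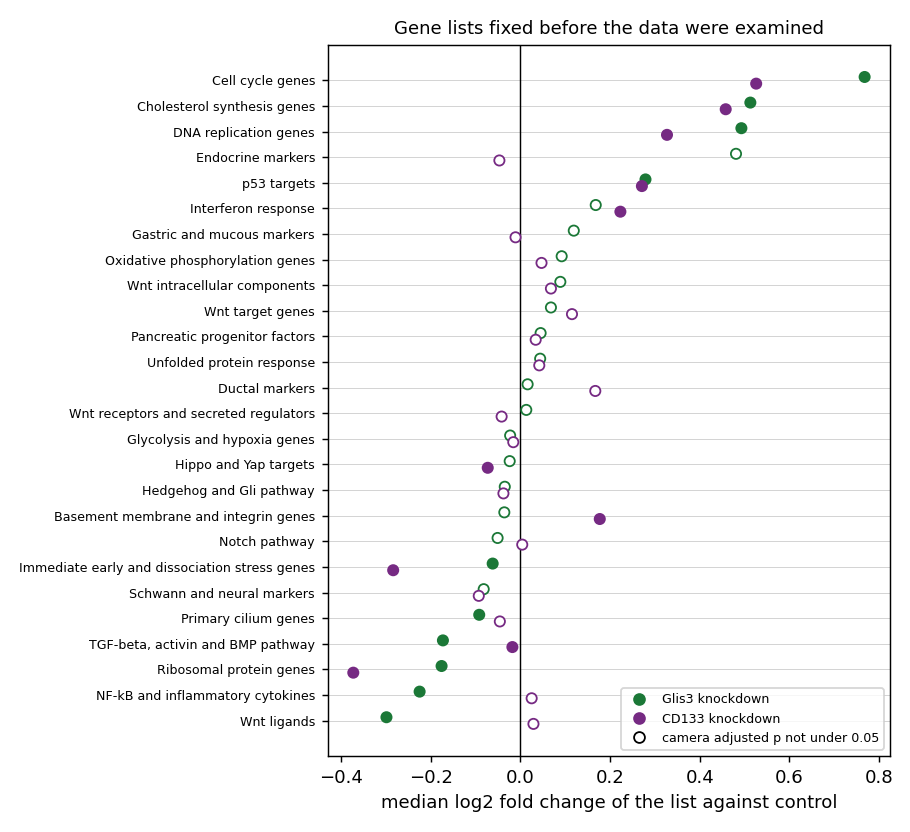
Median log2 fold change against control (x axis) of each tested gene list (y axis) in the Glis3 and the CD133 knockdown, with filled points where the camera adjusted p with the preset correlation was under 0.05. Cell cycle, DNA replication and cholesterol synthesis genes lie highest among called lists in the Glis3 knockdown (0.77, 0.49 and 0.51), and ribosomal protein genes lie lowest in the CD133 knockdown (-0.37).

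In total 884 genes rose and 394 fell in the CD133 knockdown among 10829 tested (limma), of which 27 rose and 24 fell by at least 1 on the log2 scale. At an unadjusted p under 0.05 there were 3366. The knockdown libraries lay on one side of both controls for 62.4% of tested genes, against 33.3% for exchangeable libraries. They did so for all 1278 genes called, which the threshold nearly ensures. The count was 0 without control library 1 (limma; 2444 at an unadjusted p under 0.05), 0 without control library 3 (2672), 24 without CD133 shRNA library 1 and 505 without CD133 shRNA library 3. Rises made up 69.2% of calls, but 50.4% with quantile normalization, 47.7% with median centring, 50.1% with length and GC trends removed, 76.1% with an equal RPKM sum and 58% without CD133 shRNA library 3. Camera called 10 lists, 6 higher and 4 lower, of which 0 held with an estimated correlation (1 at an unadjusted p under 0.05), and fry called 2 (7 at an unadjusted p under 0.05).

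Both knockdowns were then compared with each other's changes, since the series places Glis3 and CD133 in one pathway. Of the genes past the threshold in each, 422 rose and 131 fell in both, 553 in all, and 11 moved in opposite directions. Among the shared rises were Ces1g (3.27 in the Glis3 and 2.52 in the CD133 knockdown), B4galnt2 (1.60 and 1.27), Obp2b (1.77 and 1.18), Ugt8a (1.38 and 1.15), Atg9b (1.12 and 1.70), Mt2 (1.73 and 1.12), Ccdc33 (0.97 and 1.14), Cpm (1.48 and 0.96), Rrm2 (1.13 and 0.93) and Ndnf (0.93 and 1.62). Shared falls were led by Pglyrp3 (-2.69 and -1.92), Gpx3 (-1.90 and -1.47), Tmem178 (-1.54 and -1.45), Hp (-1.70 and -1.44), Trf (-1.73 and -1.40), Rbp4 (-1.49 and -1.36), Apcs (-1.20 and -1.33), Cyp4b1 (-1.30 and -1.17) and Mmp13 (-2.14 and -1.11). The 11 genes with opposite changes, named after their values were seen, were Ccl2 (-1.10 and 0.66), Gxylt2 (a xylosyltransferase; -1.22 and 0.54), Otop3 (a proton channel; -0.83 and 0.33), Sema3e (a semaphorin; -0.57 and 0.48), Galc, Card10, Slc16a12 and Orai2, lower in the Glis3 and higher in the CD133 knockdown, and Ttr (transthyretin; 0.47 and -0.83), the growth factor Fgf9 (0.63 and -0.51) and Serpinb6b (0.36 and -0.43), the reverse.

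Across all tested genes, the fold changes of the knockdowns had a Pearson's r of 0.64 and a Spearman's rho of 0.623, a description over genes that are not independent. Simulated unchanged groups that shared simulated controls gave a mean r of 0.503 (highest 0.601 of 100 draws). All 6 libraries were drawn, with noise independent between genes. The highest draw may therefore understate how far r can stray without an effect. Independent lists of these sizes would share 74.2 rises and 17.9 falls, but the shared controls raise the overlap above that without any shared effect, by an amount not measured here. The covariance was 0.041 against 0.005 simulated, and 73.9% of genes had the same sign against 66.6%. With 1 library per group and a different control library for each knockdown, r was 0.37 and 0.346. Differences between single libraries carry more noise than those between group means. The drop from 0.64 therefore does not measure the part that the shared controls add. The 2 controls cannot be divided into groups of 2, so the excess of r and of the covariance over the simulation is not separated from whatever these controls alone have in common. The shared count was 0 without control library 1 (limma; 1305 at an unadjusted p under 0.05 in both), 0 without control library 3 (1379), 335 without Glis3 shRNA library 3, 20 without CD133 shRNA library 1 and 282 without CD133 shRNA library 3. Of the 20 shared genes with the largest changes, 0 passed in both without control library 1 or 3, 7 without CD133 shRNA library 1 and 18 or 19 without each other library.

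**Figure D4:**
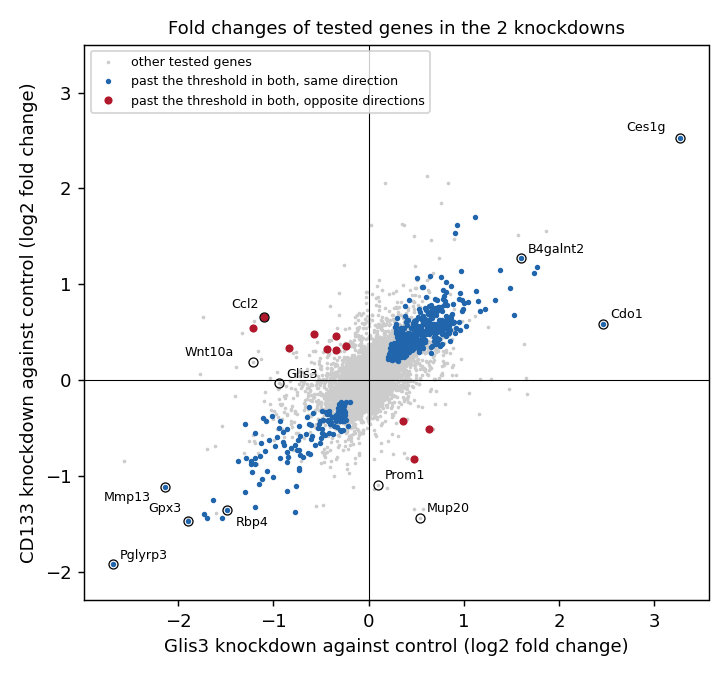
Log2 fold change against control in the Glis3 knockdown (x axis) and in the CD133 knockdown (y axis) for each tested gene, with colours for genes past the threshold in the same direction in both or in opposite directions. Pearson's r is 0.64 across genes, in part because both axes share the control libraries.

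The knockdowns were compared directly to find genes that differ between loss of Glis3 and loss of CD133. Control libraries do not enter these fold changes and act only through the variance estimate and its degrees of freedom. A call lost without a control library therefore does not reflect a change in its fold change. Glis3 itself was lower (log2 fold change -0.90, adjusted p = 0.00522) and Prom1 higher (1.19, adjusted p = 0.0041) in the Glis3 knockdown. Mup20 and Fmo2 were higher by 1.98 (SE 0.15, adjusted p = 0.00522) and 1.92 (SE 0.244, adjusted p = 0.0173), with Cdo1 at 1.87, Cytip at 1.81, Aldh3a1 at 1.64 and Sdpr (a caveolar protein, now Cavin2) at 1.52. The secreted lectin genes Reg1, Reg3g and Reg3b, close relatives of each other, were lower. Reg1 stood at 78.2 ± 41.9 RPKM in the Glis3 and 385 ± 4.59 in the CD133 knockdown (SD, n = 2 each; log2 fold change -2.40, SE 0.358, adjusted p = 0.0229), with Reg3g at -1.82 and Reg3b at -1.82. Ctla2a at -1.89, Tns1 at -1.83 and Ccl2 at -1.76 (SE 0.126, adjusted p = 0.00474) were lower as well. Of these last 12 genes, 5 passed without control library 1, 5 without control library 3, 11 without Glis3 shRNA library 3, 4 without CD133 shRNA library 1 and 7 without CD133 shRNA library 3.

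Among the Wnt ligands, Wnt10a was lower in the Glis3 than in the CD133 knockdown by a log2 fold change of -1.40 (SE 0.114, adjusted p = 0.00617) and Wnt7b by -0.39 (SE 0.065, adjusted p = 0.031), and 6 did not pass. Over the list alone 5 were lower and 1 higher. The median was -0.38 with a camera adjusted p of 0.0581 and a fry adjusted p of 0.0261, past the threshold by fry and not by camera with all 6 libraries. Camera called the list at a minimum mean of 5 RPKM and with the replicate number as a block. It also did so without Glis3 shRNA library 3 (median -0.31) and without CD133 shRNA library 3 (median -0.40). Without Glis3 shRNA library 1 both single ligands passed, and without each other library 1 did. No receptor, intracellular component or Wnt target gene passed, over all genes or over the list alone (medians 0.01, -0.03 and -0.11, camera adjusted p = 0.759, 0.288 and 0.407).

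By camera with the preset correlation, the basement membrane, inflammatory and ductal lists lay lower in the Glis3 than in the CD133 knockdown. Most of their members did not pass singly. Of 25 basement membrane and integrin genes 6 were lower, none higher and 19 not past the threshold (12 lower and 1 higher over the list alone, median -0.22), among them Lama4 at -0.88 (SE 0.103, adjusted p = 0.0142), Lama3 at -0.83, Col18a1 at -0.75 and Itga5 at -0.44. Of 25 NF-kB genes and cytokines Ccl2 and Icam1 (-0.88) were lower, the cytokine Il1a higher at 0.82, and 22 not past the threshold (15 lower and 1 higher over the list alone, median -0.26). Of 22 ductal markers 3 were lower, also over the list alone, Car2 at -0.64, Slc4a4 at -0.49 and Sox9 at -0.30 (median -0.15), and of 15 interferon genes Gbp2 (a guanylate binding protein) at -0.53 and Bst2 at -0.43, also over the list alone (median -0.10, or -0.05 with a pseudocount of 5). The camera adjusted p was 3.24e-06, 9.79e-06, 0.0148 and 0.0241, but adjusted p = 0.654, 0.654, 0.764 and 0.654 with an estimated correlation. Without control library 1 or 3 no basement membrane gene passed singly, and 1 did without Glis3 shRNA library 3, 1 without CD133 shRNA library 1 and 2 without CD133 shRNA library 3. Of the 3 NF-kB genes 1 passed without control library 1, control library 3, Glis3 shRNA library 3 or CD133 shRNA library 3, and 2 without CD133 shRNA library 1. No ductal marker passed singly without Glis3 shRNA library 3 or CD133 shRNA library 1 or 3, and 1 did without control library 1 or 3. No interferon gene passed without control library 1 or 3 or without CD133 shRNA library 1 or 3, and 1 did without Glis3 shRNA library 1 or 3. The ductal call was lost without Glis3 shRNA library 3 (median -0.07) and without CD133 shRNA library 1 (median -0.08). The interferon call was lost without Glis3 shRNA library 1 (median -0.11), with no filter on low values and at a minimum mean of 5 RPKM.

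Cell cycle and DNA replication genes lay higher as lists in the Glis3 than in the CD133 knockdown, with medians of 0.25 and 0.21 (camera adjusted p = 9.8e-07 and 2.43e-06, but adjusted p = 0.809 for both with an estimated correlation). No cell cycle gene passed singly, over all genes or over the list alone, and 1 replication gene did, the histone mRNA binding protein Slbp at 0.59. The size varied with the library left out: without Glis3 shRNA library 3 the medians were 0.08 and 0.07, without Glis3 shRNA library 1 they were 0.41 and 0.35, and without CD133 shRNA library 3 the replication median was 0.14. Ribosomal protein genes also lay higher (median 0.18, camera adjusted p = 7.5e-15, adjusted p = 0.688 with an estimated correlation), with none of 49 past the threshold over all genes and 17 higher over the list alone. Immediate early genes had a median of 0.16, with Socs3 at 0.64 and the transcription factor Klf6 at 0.45 higher and 23 not past the threshold (6 higher and 1 lower over the list alone). Their camera adjusted p was 0.00596 (adjusted p = 0.809 with an estimated correlation), a call lost without Glis3 shRNA library 1 (median 0.14).

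Single genes of other lists differed between the knockdowns, with no call for the list by camera. Of 30 TGF-beta pathway genes 2 were higher and 4 lower, with the ligand Tgfb2 at 0.95 and Tgfb1 at -0.94 in opposite directions (4 and 7 over the list alone, median -0.05, adjusted p = 0.457). Foxj1, a regulator of motile cilia, was the 1 member of the primary cilium list past the threshold, at -1.07 (SE 0.153, adjusted p = 0.0222). That list had a median of -0.03 (camera adjusted p = 0.475) and the same count over the list alone. Of 25 Hippo and Yap genes 1 was higher and 3 lower, with Nuak2 at -0.78 and Ankrd1 at -0.63 (3 and 3 over the list alone, median 0.02, adjusted p = 0.699). Nrarp, at -0.54, was the 1 of 22 Notch genes (2 and 2 over the list alone, median 0.03 against a mean of -0.01, adjusted p = 0.987). No Hedgehog gene passed (1 and 2 over the list alone, median 0.02 against a mean of -0.07, adjusted p = 0.987). Of 20 progenitor factors Nr5a2 (a nuclear receptor) was higher at 0.59, and Sox9 and Hnf4a lower (4 and 3 over the list alone, median -0.08, adjusted p = 0.658). Cpe, at -0.41, was among 2 of 7 endocrine markers that were lower (3 and 2 over the list alone, median 0.04 and mean 0.47, adjusted p = 0.922). Their median was -0.08 without Glis3 shRNA library 1 and 0.17 without Glis3 shRNA library 3. Aqp5 was higher at 0.79 beside the Reg3 genes among 10 gastric markers (3 and 3 over the list alone, median 0.29, adjusted p = 0.658). Of 5 neural markers Ncam1 and Nes were lower at -0.86 and -0.76 (1 and 2 over the list alone, median 0.04 against a mean of -0.26, adjusted p = 0.527). Of 25 genes of the p53 list 1 was lower, the cyclin-dependent kinase inhibitor Cdkn2b at -0.26 (1 and 1 over the list alone, median -0.05 against a mean of 0.02, camera adjusted p = 0.936). Ppp1r15a was higher at 0.50 among 25 unfolded protein response genes (2 over the list alone, median 0.02, adjusted p = 0.787). Acat2 (an acetyl-CoA acetyltransferase) was higher at 0.38 among 25 cholesterol synthesis genes (2 over the list alone, median 0.04, adjusted p = 0.206). The cholesterol list was called higher without CD133 shRNA library 1 (median 0.12). No glycolysis or oxidative phosphorylation gene passed, over all genes or over the list alone (medians -0.01, against a mean of 0.01, and 0.05, adjusted p = 0.922 and 0.172). Each single-gene call of these lists was lost without control library 1, control library 3 or CD133 shRNA library 1.

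In the direct comparison 174 genes were higher and 266 lower in the Glis3 knockdown among 10829 tested (limma), of which 16 and 27 by at least 1 on the log2 scale, and 2373 had an unadjusted p under 0.05. The groups lay apart in 54.7% of tested genes, against 33.3% for exchangeable libraries, a share from which genes that are not independent can stray. The count of 440 was 56 without control library 1, 58 without control library 3, 743 without Glis3 shRNA library 1, 110 without Glis3 shRNA library 3, 25 without CD133 shRNA library 1 and 98 without CD133 shRNA library 3. The changes in this count without a control library come from the variance estimate and its degrees of freedom, since controls do not enter the fold changes. Camera called 8 lists, 4 higher and 4 lower, of which 0 held with an estimated correlation (1 at an unadjusted p under 0.05), and fry called 1, the Wnt ligands (5 at an unadjusted p under 0.05).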

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

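The alternative that removes length and GC trends was chosen after seeing the data; the others were planned. No named gene past the threshold and no target changed direction under another pseudocount, filter, scaling or variance setting; where the knockdown libraries lie on one side of both controls, leaving out 1 library cannot turn a direction. Among lists called by camera, the median changed sign for immediate early genes in the Glis3 knockdown without control library 1 and for TGF-beta genes in the CD133 knockdown with an equal RPKM sum. Medians near 0 of many lists that were not called changed sign under some scalings or without some libraries. A pseudocount of 5, which shrinks changes of genes with low values, lowered the medians of cell cycle (0.348) and DNA replication genes (0.207) in the CD133 knockdown and of cholesterol synthesis genes (0.32) in the Glis3 knockdown, with the calls kept. Among results of lists, 1458 kept their side of the threshold, 77 lost and 19 gained a call. Among named genes the numbers were 4083, 1072 and 22, and among counts, correlations and targets 152 stayed within 1.5 times or their spread, 42 moved and 2 lost a call. With genes of at least 5 RPKM, 913 genes passed in the Glis3 knockdown, with fewer genes tested. With the replicate number as a block, 608 passed in the Glis3 knockdown, 335 in the CD133 knockdown, 79 between them and 149 in both knockdowns. Deviations of libraries with one number correlated at -0.37 (control and Glis3 knockdown), -0.43 (control and CD133 knockdown) and 0.03 (the knockdowns). Equal numbers thus did not behave as pairs. The first 2 values are not near 0, so the control libraries differed partly in the same genes as the libraries of each knockdown, with the numbers crossed. The model treats libraries as independent, and the source of this pattern was not tested. With only the compared groups in the fit, which leaves fewer samples, 58 passed between the knockdowns. At an adjusted p under 0.10 the counts were 2369, 2379, 973 and, shared, 1141. With a log2 fold change of at least 1 they were 84, 51, 43 and 19. Leaving out 1 library at a time gave 21 to 1334 genes for the Glis3 knockdown, 0 to 1657 for the CD133 knockdown, 25 to 743 between them and 0 to 592 shared. The correlation of the knockdowns then lay between 0.558 and 0.681. From single libraries with separate controls it was 0.37 and 0.346. Prom1 in the CD133 knockdown ranged from -1.155 to -1.031 (adjusted p up to 0.0737). The lone sample left in a group is assumed to vary like the other groups. Leaving out a library also leaves fewer than 3 residual degrees of freedom and less precision for its group, which by itself can remove calls. Prom1 fell by more without control library 1 (-1.137) than with all libraries (-1.093), yet lost its call. How much of the shifts in counts came from this loss of precision, and how much from the library left out, was not tested. Lists called numbered 0, 0 and 0 with an estimated correlation and 1, 2 and 1 by fry. With 3 residual degrees of freedom behind its p, camera with an estimated correlation could call few lists whatever their correlation. With length and GC trends removed, 1738, 1549 and 639 genes passed, 730 in both, with r = 0.648. For the block the cause was not tested. At this depth genes near 1 RPKM rest on few reads, and their changes are poorly measured.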

Other observations

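The lists of motile cilium, acute phase, xenobiotic and detained-intron genes, and their tests, were chosen only after the fold changes were seen. Members already seen were left out of each test, except Aldh1a1. That gene, given above at 0.54 among progenitor factors, stayed in the xenobiotic list and counts among its rises. Some other members are close paralogs of seen ones, such as Gsta4 of Gsta1, and are not a separate check. Values with 1 library left out are not given for these lists. Their camera p-values are unadjusted, unlike those of the lists fixed beforehand, and are not comparable with them. Part of the motile cilium list fell with Foxj1 in the Glis3 knockdown. Of 27 members not seen before, 6 fell and 21 did not pass (median log2 fold change -0.27, n = 2 per group). Among the falls were the axonemal and radial spoke genes Iqcg at -0.89, Rsph1 at -0.82, Enkur at -0.75 and Cfap43 at -0.73. Control means of these named genes were low, from 2.79 (Enkur) to 4.605 RPKM (Cfap43). The camera p was 2.96e-06 (p = 0.0965 with an estimated correlation), while in the CD133 knockdown 1 fell (median -0.03, p = 0.0556) and the list lay lower in the Glis3 than in the CD133 knockdown (camera p = 0.000169, p = 0.15 with an estimated correlation).

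Some acute phase genes fell and some drug-metabolizing enzymes rose in the Glis3 knockdown. Of 11 acute phase and complement genes not seen before, Cp (ceruloplasmin) fell by 0.96, Hpx (hemopexin) by 0.81 and Stat3 by 0.48, Ifitm3 rose by 0.53 and 7 did not pass (median -0.23, camera p = 0.0157, p = 0.284 with an estimated correlation). In the CD133 knockdown these 11 genes had a like median of -0.24 (camera p = 0.0169, p = 0.289 with an estimated correlation), with 2 rises and 1 fall, and camera gave p = 0.459 between the knockdowns. Of 47 xenobiotic and glutathione enzymes, 16 rose, 2 fell and 29 did not pass (median 0.18, camera p = 0.00203, p = 0.334 with an estimated correlation), with Nqo1 (a quinone reductase) at 0.89, Gsta4 at 0.78, Srxn1 (sulfiredoxin) at 0.57 and Ephx1 (an epoxide hydrolase) at 0.55, and Hmox1 (heme oxygenase) and Ugt1a7c at -0.27 and -0.20. In the CD133 knockdown 6 of these 47 rose and 3 fell (camera p = 0.134), and between the knockdowns camera gave p = 0.0254 (p = 0.466 with an estimated correlation).

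The joint fall of ribosomal protein genes in the CD133 knockdown (median -0.37) was weighed against 3 technical explanations. Short, abundant transcripts in general did not fall: 96 genes matched in length and RPKM had a median of 0.028 (bootstrap 95% interval 0.002 to 0.077), although their median RPKM of 190 stayed below the 331 of the ribosomal protein genes. Scaling did not remove the fall, since the highest list median under 3 scalings was -0.24. Detained-intron and nuclear transcripts rose, 10 of 28 not seen before (median 0.29, camera p = 1.34e-05, p = 0.277 with an estimated correlation), such as Ccnl2 at 0.73 and Clk1 at 0.64, so a larger share of nuclear or incompletely spliced RNA may contribute. These transcripts were as high in the Glis3 knockdown (median 0.28), where the ribosomal protein median was -0.18, so they track the difference between the knockdowns poorly, and an effect of CD133 itself stays open.

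Cell cycle genes rose in both knockdowns. If 1 control library alone stood apart, the rise would vanish without it, but the lowest list median without either control was 0.495. The lowest median under quantile normalization, median centring and an equal RPKM sum was 0.466, while a pseudocount of 5, which is no scaling of libraries, gave 0.348 in the CD133 knockdown. Both knockdowns differ from control in the use of an shRNA pool, and a shared effect of pools or of 1 control vector cannot be separated from an effect of the targets by these 6 libraries.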
